A study of Mus musculus with 3 samples.

How the data were processed

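RNA was measured on 3 Agilent 2-colour mouse expression arrays, each with cRNA of wild-type embryoid bodies in 1 dye and of mutant+CT embryoid bodies in the other. Per the labels, the 3 biological replicates of each condition were cultured in parallel for 10 days in suspension without LIF, 1 µg of RNA was amplified, 300 ng of cRNA per dye were hybridised, and the dyes were swapped on replicate 2. The 3 arrays lie on 1 slide and were scanned once, per the file headers.

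The deposited scanner files hold intensity values: mean brightness of each spot and median of its local background in green (Cy3) and red (Cy5), written by Agilent Feature Extraction 10.7.3.1 per the file headers. The same files hold Agilent's processed intensity, with background subtraction, detrending and dye normalization per the file headers, and a deposited log10 ratio of red over green, used here only to find the direction of the value table. The deposited value table holds log2 ratios that the authors normalized, with limma per the submitters' processing notes; the exact steps and versions are unknown. Its columns have medians of -0.02, 0.01 and -0.01, run as mutant+CT over wild type, and follow the ratios computed here with slopes of 1.03, 0.97 and 0.97 and correlations of 0.994, 0.996 and 0.998.

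Ratios were computed from the spot intensities in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected with normexp (offset 50), dyes were normalized within each array with loess, control spots had weight 0, and spots marked as outliers in the files (454, 234 and 507 on replicates 1 to 3) were set to missing. Ratios were turned so that all read mutant+CT over wild type. Median green signals were 227, 200 and 226 and median red signals 144, 180 and 200, over local backgrounds of 41, 43 and 44 in green and 36.5, 37.5 and 38 in red. The SD of the log2 ratios of genes was 0.77, 0.74 and 1.02. A probe was kept when it was well above background, as marked in the files, on all 3 arrays in wild type or in mutant+CT, which kept 26317 of 39429 probes. Gene names came from the RefSeq annotation of GRCm38.p6, used for names alone, by accession (30708 of 43020 spots; 15265 of 20389 genes), and otherwise from the files, and positions are the files' mm9 coordinates. Each gene is represented by its brightest kept probe. Where 1 group is not well above background (124 genes), a fold is a lower bound, written "at least".

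Log2 ratios were tested against 0 with limma's moderated t-test and Benjamini-Hochberg adjustment over 20389 genes at adjusted p under 0.05, and Dido1 probes over all kept probes. Genes at least 2-fold apart on every array were counted without a test. The 28 gene lists, whose camera results are all printed below, needed at least 5 measured members and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Camera compares a list with all other genes; fry's p tests whether a list moves on balance one way and its mixed p whether members move either way, and neither compares with other genes. Named by rule are Dido1, the 10 genes with the smallest p in each direction, and the member with the smallest p of each list. Groups, tests, lists, the naming rule and most of the alternatives were fixed before the data were examined.

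The steps were tested on simulated data with 50 changed genes per size: 0, 15, 42 and 45 were recovered at adjusted p under 0.05 for log2 changes of 1, 2, 3 and 4, with 4 false calls among 20189 unchanged genes. Of 4 shifted lists, 4 were found with the preset and 0 with the estimated correlation, with 0 false calls. Genes were simulated as independent, so this does not check the preset correlation where members of a list move together. Alternatives were no background subtraction, Agilent's processed signals, median centring, quantile normalization of average intensities between arrays, no filter on dim probes, the filter in both channels, the mean of all probes, the deposited table, a dye term, a trended and robust variance prior, an adjusted p under 0.1, a 2-fold threshold, leaving out each array, and, added after the results were seen, leaving out GAA-repeat probes, scaling the arrays to the same spread and a separate-channel fit with its correlation estimated without the dye term. The number of arrays limits the precision.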

Results

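Gene expression was measured in mouse embryoid bodies, floating aggregates of embryonic stem cells that form many cell types once LIF, the cytokine that keeps them undifferentiated, is left out. After 10 days, wild-type embryoid bodies were set against embryoid bodies whose Dido3 protein lacks its C-terminal region and which also overexpress that missing region, encoded by exon 16. The latter are called mutant+CT here. Dido3 is the longest product of Dido1, and per its title the series concerns the choice between self-renewal and differentiation. The comparison asks which transcripts differ between embryoid bodies with the split protein and wild-type ones. No sample carried the deletion alone or the construct alone. Their effects cannot be told apart, nor from other differences between the cells of the groups. The labels give 3 biological replicates per condition, and each of 3 arrays carried 1 wild-type and 1 mutant+CT RNA, with wild type in Cy5 on replicates 1 and 3 and in Cy3 on replicate 2. Values below are log2 ratios of mutant+CT over wild type, as mean ± SD over the 3 arrays, unless stated otherwise. Between 68.2% and 78.5% of the spots of a channel were well above background, no spot was saturated, and 20389 genes were tested. The number of arrays limits the precision. Genes are not independent replicates. Across them replicates 1 and 3 correlated at 0.54, 2 and 3 at 0.38 and 1 and 2 at 0.18 (Pearson). By rank the values were 0.54, 0.24 and 0.06 (Spearman). The pair with the highest correlation shares a dye orientation. In limma with a dye term, the dye coefficient had an unadjusted p under 0.05 for 2271 genes and an adjusted p under 0.05 for 0. Replicate 2 is alone in its orientation, so a dye effect cannot be told from a difference of that replicate.

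The targeted gene, Dido1, gave a different ratio at each of its 4 probes. Listed from the 5' to the 3' end of the transcripts, which lie on the minus strand of chromosome 2 (coordinates of mm9), probe A_55_P2430472 at 180419747 to 180419806 matches transcript variants 1, 2 and 3 and had a ratio of 1.79 ± 0.33 (SD, n = 3). Probe A_52_P226127 at 180415861 to 180415920, of variant 1, had a ratio of -2.39 ± 1.29, with -3.85, -1.40 and -1.93 on the 3 arrays. Probe A_66_P128564 at 180405604 to 180405663, of variant 2, rose by 3.53 ± 0.12, or 11.6-fold. Probe A_51_P336385 at 180393086 to 180393145, of variant 3, the most 3' one, had a ratio of 0.77 ± 0.80, with -0.01, 1.58 and 0.74 on the 3 arrays. In limma over all kept probes with Benjamini-Hochberg adjustment, the variant 2 probe passed with adjusted p = 0.0436, and the others had adjusted p of 0.0645, 0.116 and 0.360 in the order above. The call of the variant 2 probe ended with a dye term in the model (adjusted p = 0.118), without replicate 2 (0.0917) and without replicate 3 (0.125), where its ratio was 3.53, 3.54 and 3.47. Agilent's processed signals called the probe shared by the variants as well (limma, adjusted p = 0.0317). No annotation of mm9 was used here, so the place of each probe relative to exon 16 is not determined, and a probe outside the deleted part does not check the labels.

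**Figure D1:**
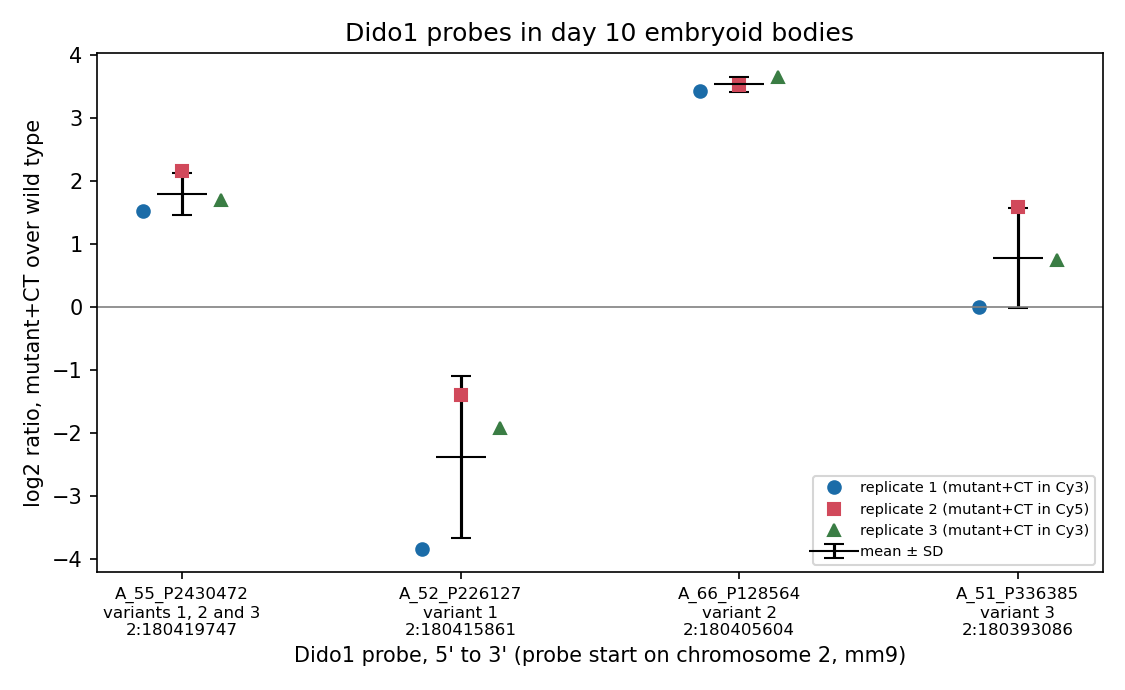
The vertical axis is the log2 ratio of mutant+CT over wild type, and each column is 1 Dido1 probe, ordered from 5' to 3' by its mm9 start on chromosome 2; points are the 3 arrays and bars the mean ± SD. The variant 2 probe lies between 3.42 and 3.66 on all arrays, and the variant 1 probe lies below 0 on all of them.

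Among single genes, the 10 higher ones with the smallest p are given first. Xlr5c and Xlr5b, X-linked paralogs of the Xlr family, had ratios of 5.18 ± 1.10 and 5.14 ± 0.91 (SD, n = 3), and their probes may not tell the copies apart. Ctsj, a placental cathepsin, had 3.43 ± 0.41 and Prl4a1, a placental prolactin-family hormone, 2.82 ± 0.29. Rest, a repressor of neuronal genes, had 3.32 ± 0.44, Trim71, an RNA-binding protein of stem cells and embryos, 2.68 ± 0.40, Atp7a, a copper transporter, 3.57 ± 0.57, and Slc3a1, a subunit of an amino acid transporter, 2.47 ± 0.12. Gigyf1 had 3.002 ± 0.31 and Tmem245 3.27 ± 0.38. A second probe disagreed for Rest (0.29) and for Gigyf1 (0.03), so the mean of all probes was 1.80 and 1.51, while another probe gave 2.51 for Trim71 and 4.62 for Xlr5c. The second probes of Rest and Gigyf1 were dimmer, so their ratios may understate a difference. Mean log2 intensities were 6.75 against 11.69 for Rest and 7.516 against 10.87 for Gigyf1. On Agilent's processed signals the ratio was 4.37 for Prl4a1 and 3.94 for Slc3a1.

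The 10 lower genes with the smallest p include Paip1, which binds the poly(A)-binding protein (-3.93 ± 0.22, SD, n = 3), and Eef1akmt2, a methyltransferase of the elongation factor eEF1A (-3.58 ± 0.35). Rax, a homeobox gene of the eye field and hypothalamus, had -2.50 ± 0.35, Nrcam, a neuronal cell adhesion molecule, -2.18 ± 0.29, and Spock1, a proteoglycan, -2.05 ± 0.19. Pop4, a subunit of RNase P, had -2.31 ± 0.22, Neil1, a DNA glycosylase, -2.13 ± 0.25, and Irf4, a transcription factor of lymphocytes, -2.19 ± 0.28, and -4.02 on Agilent's processed signals. Vsig2 had -2.16 ± 0.19 and Gon4l -1.99 ± 0.11. The probes of some genes disagreed: another probe gave -0.27 for Paip1 and -0.37 for Spock1, and the others of Gon4l gave 0.82 and -0.09, so the mean of all probes was -2.10, -1.21 and -0.42, whereas that of Eef1akmt2 gave -3.41 and that of Vsig2 -1.96. The probes at -0.27, -0.37 and -0.09 were dim, with mean log2 intensities of 7.475, 6.702 and 6.918. Their ratios may understate a difference. Of 4815 genes with several kept probes, 15 had a probe at least 2-fold higher and another at least 2-fold lower. That count leaves out genes with another probe near 0, such as Paip1 and Spock1, so it does not measure how often probes disagree. Of 11 genes with probes on the Y chromosome, which had a median of -0.16, 2 were at least 2-fold lower and 1 at least 2-fold higher on every array, the transcript ENSMUST00000172100 (2.07 ± 1.35). RefSeq places 4 of the tested genes on Y: Ddx3y, an RNA helicase, had -4.02 ± 1.18, Rbmy -2.38 ± 0.96 and Uty -1.44 ± 0.50, and Ube1y1 had 0.12 ± 0.34. Ddx3y was well above background in mutant+CT on 1 array and Rbmy and Uty on none, so their ratios understate the difference, and Y-linked genes were chosen after their values were seen.

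None of these genes passed the test over all genes. With limma and Benjamini-Hochberg adjustment, 0 of 20389 genes had an adjusted p under 0.05, the smallest was 0.0735, the 20 genes above, the Y-linked ones aside, had adjusted p of 0.0735 to 0.0737, and 3212 genes had an unadjusted p under 0.05. At an adjusted p under 0.1 there were 296 genes, 203 higher and 93 lower. The count of 0 depended on the setting: limma called 290 genes (184 higher, 106 lower) on Agilent's processed signals, 218 in a separate-channel fit, 176 with a trended and robust variance prior, 12 where only probes above background in both channels were kept, and 196 without replicate 1, and 0 without replicate 2, without replicate 3 and with a dye term.

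By size alone, 589 genes were at least 2-fold apart on every array, 387 higher in mutant+CT and 202 lower. They include 6 of 7 measured members of the Xlr3, Xlr4 and Xlr5 group and 8 of 15 members of the prolactin family, all higher, and 1 of 18 members of the Rhox family, Rhox8, whose probe holds a GAA run of 44 bases. These 3 families were chosen after their values were seen. A gene has the same sign on all 3 arrays in 25% of cases by chance, and 4141 genes were higher and 3554 lower on every array. This count has no test of its own, and in simulated data 72 of 20189 unchanged genes were 2-fold apart on every array. It was 1193 on Agilent's processed signals, of which 578 were among the 589, and over 2 arrays it was 1273 without replicate 1 and 1537 without replicate 2. Without probes that hold a GAA run of 12 or more bases it was 538, 336 higher and 202 lower.

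Gene lists fixed for the cell types and states of embryoid bodies were compared next. Of 28 lists, 14 passed camera, limma's test of a list against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. With an estimated correlation 0 lists passed and the smallest adjusted p was 0.529, and 0 passed with fry, which tests whether a list's genes move on balance one way (smallest adjusted p = 0.170). For movement of members in either direction, fry's mixed test passed 12 of 28 lists, with adjusted p = 0.0132 for interferon response and for endothelium, 0.0263 for primed epiblast, 0.0265 for epithelium, 0.0409 for macrophages, 0.0435 for cholesterol synthesis, imprinted genes and primitive and parietal endoderm, and 0.0447 for definitive endoderm, neural crest, trophoblast and visceral endoderm. It does not compare a list with other genes. Of every list, 0 members passed limma over all genes, so the counts of members below are given both that way and adjusted over the list alone. The member with the smallest p of each list was named by a fixed rule, and the other members were chosen after their values were seen.

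**Figure D2:**
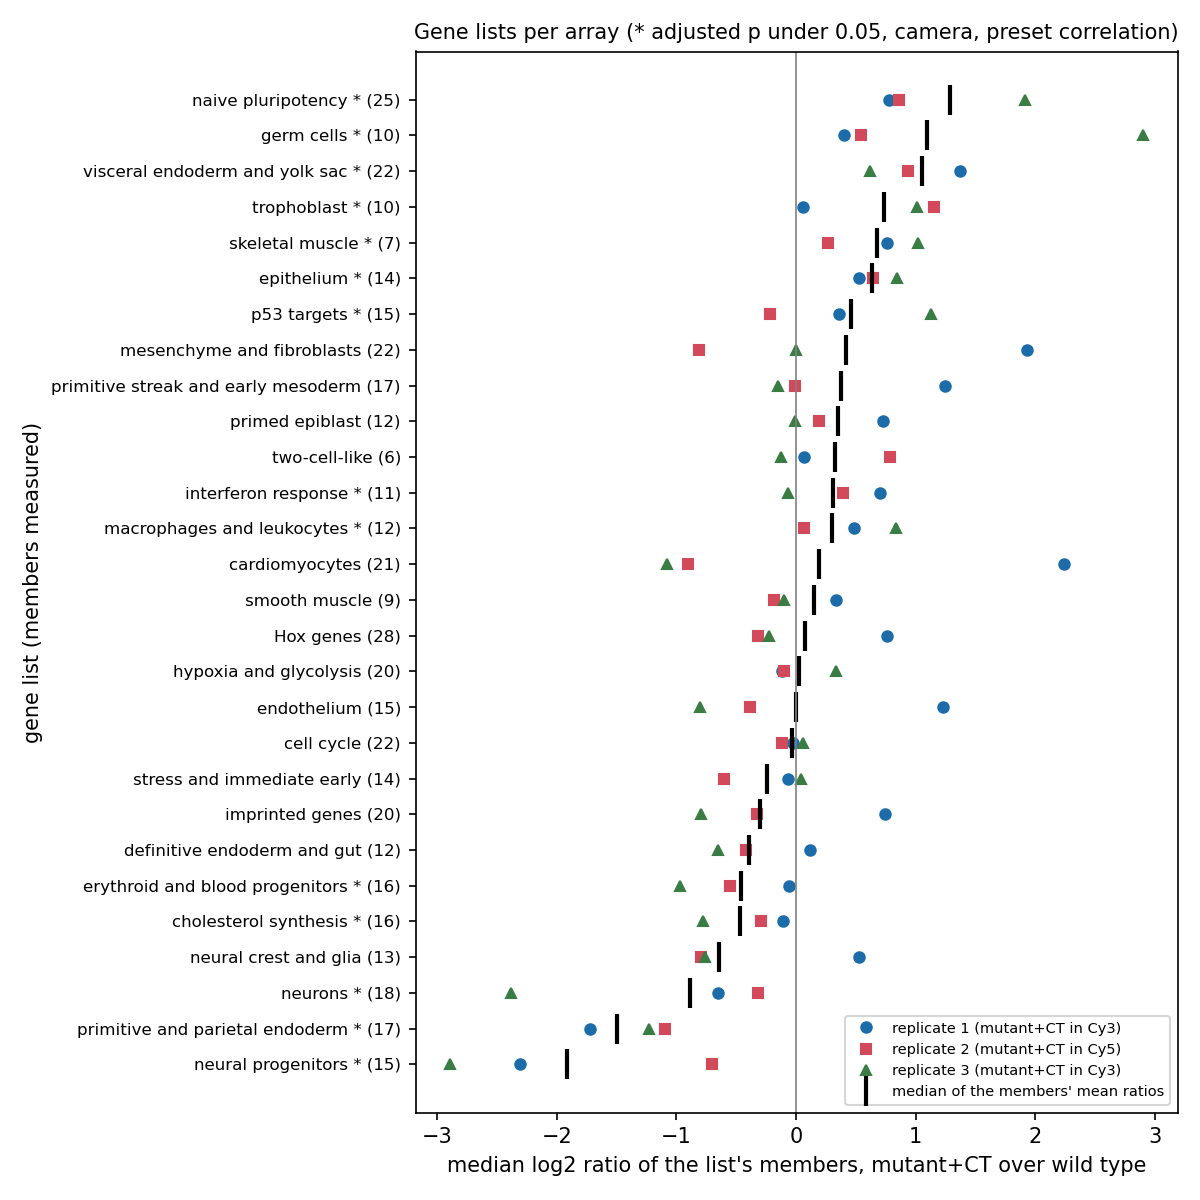
The horizontal axis is the median log2 ratio of mutant+CT over wild type of each list's members and the vertical axis the 28 lists with the number of members measured; points are the 3 arrays, bars the median of the members' mean ratios, and stars mark adjusted p under 0.05 in camera with the preset correlation. The medians run from -1.91 for neural progenitors to 1.28 for naive pluripotency, and for cardiomyocytes replicate 1 lies at 2.24 against -0.91 and -1.08.

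Markers of naive pluripotency, the state of undifferentiated stem cells, were higher in mutant+CT as a list, with a median of 1.28 and 19 of 25 members higher on every array. Nr0b1, a nuclear receptor of stem cells, had 2.67 ± 0.91 (SD, n = 3), Tcl1, a cofactor of Akt, 2.47 ± 1.40, Zfp42 (Rex1) 2.17 ± 1.22 and Dppa2, the member with the smallest p, 1.65 ± 0.17. Pou5f1 (Oct4) had 1.26 ± 0.61, while the core factors Sox2 and Nanog had 0.16 ± 0.62 and 0.09 ± 0.09 and Klf4 had -0.68 ± 1.01. The Nanog probe was dim, with a mean log2 intensity of 6.785, so its ratio may understate a difference. Adjusted over the list alone, 13 members rose, 0 fell and 12 did not pass, and over all genes 0 of 25 passed (limma). The list passed camera with adjusted p = 4.82e-09, and adjusted p = 0.790 with an estimated correlation. The primed epiblast list, of the stage that follows, moved both ways, with a median of 0.35 (camera adjusted p = 0.677, and adjusted p = 0.830 with an estimated correlation). Sox3 and Zic2, which are also active in early neural tissue, fell by 2.19 and 1.77 adjusted over the list alone, as did Zic5 by 0.79, whereas Nodal (1.30 ± 0.35), Sox4, Dnmt3b and Foxd3 rose, 5 of 12 members did not pass, and over all genes 0 passed.

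Both extraembryonic endoderm lists moved, in opposite directions. Primitive and parietal endoderm genes, which include the basement membrane that parietal cells lay down, had a median of -1.495, and 14 of 17 members were lower on every array. Thbd had -2.996 ± 1.58 (SD, n = 3), the collagen Col4a1, with the smallest p, -2.68 ± 1.02, the laminin Lama1 -2.44 ± 1.02, and the transcription factor Sox7 -1.48 ± 0.77. The sign of Sparc was different, at 0.17 ± 0.35. Adjusted over the list alone 13 members fell, 0 rose and 4 did not pass, and over all genes 0 passed (limma), and camera gave adjusted p = 3.96e-10, and adjusted p = 0.529 with an estimated correlation. Visceral endoderm and yolk sac genes, many of which encode secreted transport proteins, had a median of 1.05, and 15 of 22 were higher on every array. Trf (transferrin) had 2.24 ± 1.09, the apolipoprotein Apoa1, with the smallest p, 2.12 ± 0.58, Afp (alpha-fetoprotein) 1.55 ± 1.03 and Hnf4a 1.10 ± 0.29. Adjusted over the list alone 12 members rose and 1 fell, the endocytic receptor Lrp2 at -1.08 ± 0.43, 9 did not pass, and over all genes 0 passed. Camera gave adjusted p = 1.77e-06, and adjusted p = 0.790 with an estimated correlation. The definitive endoderm and gut list had a median of -0.39 and did not pass (camera adjusted p = 0.366, and adjusted p = 0.830 with an estimated correlation). Foxa3 rose by 1.27 ± 0.13 adjusted over the list alone, the other 11 of 12 members did not pass, and over all genes 0 passed.

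Neural progenitor genes had the lowest median of all lists, at -1.91, and 11 of 15 members were lower on every array. The medians were -2.30, -0.70 and -2.89 on replicates 1, 2 and 3, so the shift was smallest on the dye-swapped replicate 2. Fabp7, a lipid-binding protein of radial glia, had -4.24 ± 2.02 (SD, n = 3), Hes5, a Notch target with the smallest p, -3.92 ± 1.49, and the transcription factors Pax6 and Sox1 -3.19 ± 1.35 and -3.11 ± 1.37. Adjusted over the list alone 11 members fell, 0 rose and 4 did not pass, among them Nes (-1.28 ± 1.51), and over all genes 0 passed (limma). The list passed camera with adjusted p = 3.26e-10, and adjusted p = 0.790 with an estimated correlation. On Agilent's processed signals the median was -3.16. Neuron genes had a median of -0.88 with camera adjusted p = 0.00569, and adjusted p = 0.821 with an estimated correlation. Dcx, a microtubule protein of young neurons, had -3.07 ± 2.12, Stmn3 -2.27 ± 1.32 and Map2 -2.19 ± 1.70, while Elavl3, the RNA-binding protein with the smallest p, had 1.17 ± 0.30. Of 18 members 8 were lower and 3 higher on every array, and 0 passed, adjusted over the list alone or over all genes. The median was -0.53 without replicate 3, and the list still passed. The neural crest and glia list did not pass, with a median of -0.64 (camera adjusted p = 0.249, and adjusted p = 0.821 with an estimated correlation). Pax3 (-1.99 on Agilent's processed signals) and Tfap2a fell by 1.16 and 1.75 and Foxd3 rose by 0.89 adjusted over the list alone, the other 10 of 13 members did not pass, and over all genes 0 passed. Without replicate 1 this list was called (median -0.97, camera adjusted p = 0.000717), and without replicate 2 its median was 0.05.

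The mesodermal lists mostly differed between the arrays. Cardiomyocyte genes had medians of 2.24, -0.91 and -1.08 on replicates 1, 2 and 3. Hand2, a heart transcription factor, had 4.39, -2.60 and -2.80, the myosin light chain Myl7 4.05, -1.78 and -1.71, and the actin Actc1 3.79, -1.42 and -1.76. Myl3, with the smallest p, had -1.40 ± 0.89 (SD, n = 3). Mesenchyme and fibroblast genes had medians of 1.93, -0.81 and 0.00, with 4.54, -2.16 and -1.93 for the collagen Col3a1, while Fn1 (fibronectin), with the smallest p, had 1.12 ± 0.56. Over the 3 arrays the cardiomyocyte median was 0.19 (camera adjusted p = 0.593, and adjusted p = 0.940 with an estimated correlation) and the mesenchyme median 0.41 (camera adjusted p = 0.239, and adjusted p = 0.851 with an estimated correlation), and of their 21 and 22 members 0 passed, adjusted over the list alone or over all genes. Without replicate 1 both medians turned, to -0.99 (camera adjusted p = 5.1e-06) and -0.61 (0.00444), whereas cardiomyocytes had 0.89 without replicate 3 (0.0265) and mesenchyme 1.15 without replicate 2 (0.0181).

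Primitive streak and early mesoderm genes had a median of 0.37 and 0 of 17 members passing, adjusted over the list alone or over all genes (camera adjusted p = 0.159, and adjusted p = 0.821 with an estimated correlation). Cdx1, a posterior homeobox gene with the smallest p, had 0.83 ± 0.43 (SD, n = 3), and T (Brachyury) had 2.22, -0.86 and -1.69 on the 3 arrays. The median was -0.09 without replicate 1, and without replicate 3 the list was called (median 0.44, camera adjusted p = 0.0134). Hox genes, which set position along the body axis, had a median of 0.07 with 0 of 28 passing either way (camera adjusted p = 0.576, and adjusted p = 0.908 with an estimated correlation). Hoxb9 had 2.20 ± 1.24 and Hoxa2 -0.64 ± 0.36. The Hox median was below 0 without replicate 1 (-0.11), on Agilent's processed signals (-0.03) and with a dye term (-0.03).

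Among muscle lists, skeletal muscle had a median of 0.68 and smooth muscle 0.15. Myh3, an embryonic myosin, had 1.43 ± 0.77 (SD, n = 3), Tnnt3 (troponin T) 0.71 ± 0.39, and Smtn (smoothelin) of the smooth muscle list 0.50 ± 0.17. The skeletal list passed camera with adjusted p = 0.0282, and adjusted p = 0.790 with an estimated correlation, and 0 of 7 members passed, adjusted over the list alone or over all genes. Its call ended without replicate 1 (median 0.53, camera adjusted p = 0.0529), without replicate 3 (0.48, 0.0903), with no filter on dim probes (0.19, 0.0655) and with a dye term (0.36, 0.0593). Smooth muscle did not pass (camera adjusted p = 0.958, and adjusted p = 0.964 with an estimated correlation), with 0 of 9 members passing either way, and its median was -0.32 without replicate 1, -0.07 with a dye term and -0.01 with no filter on dim probes.

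In the erythroid and blood progenitor list the embryonic globins had the lowest ratios. Hbb-bh1 fell by 3.30, Hba-x by 3.09 and the alpha globin Hba-a1 by 2.08 adjusted over the list alone, whereas Itga2b (CD41), the member with the smallest p, rose by 1.08 ± 0.16 (SD, n = 3) and Car2 (carbonic anhydrase 2) by 0.97 ± 0.28, and Gata1 had 0.15 ± 0.96. The other 11 of 16 members did not pass, and over all genes 0 passed (limma). The list had a median of -0.46 and passed camera with adjusted p = 0.0450, and adjusted p = 0.821 with an estimated correlation. The call ended without replicate 2 (adjusted p = 0.254), without replicate 3 (0.0527), with median centring (0.0587), with no filter on dim probes (0.0621), with the filter in both channels (median -0.26, 0.0798), with the mean of all probes (0.0516) and with a dye term (0.115), and the median was -0.81 without replicate 1 and -1.14 on Agilent's processed signals, where Itga2b had 1.62. Macrophage and leukocyte genes had a median of 0.30 (camera adjusted p = 0.0327, and adjusted p = 0.790 with an estimated correlation). Laptm5, a lysosomal protein of blood cells with the smallest p, rose by 1.56 ± 0.42 and Csf1r, the receptor of a macrophage growth factor, by 1.28 ± 0.51 adjusted over the list alone, 10 of 12 members did not pass, and over all genes 0 passed. Ctss, a cathepsin not well above background in wild type, was at least 3.69-fold higher in mutant+CT and did not pass. The list's call ended without replicate 3 (median 0.22, camera adjusted p = 0.0748), with the filter in both channels (0.09, 0.292) and with the mean of all probes (0.30, 0.0516), and the median was 0.67 on Agilent's processed signals, where Laptm5, well above background in wild type on 1 array, had 4.75.

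The endothelial list held 3 members that rose adjusted over the list alone: Robo4, a vascular receptor with the smallest p (2.04 ± 0.16, SD, n = 3), Pecam1 (CD31, 1.26 ± 0.57) and Eng (endoglin, 1.04 ± 0.16). The other 12 of 15 did not pass, over all genes 0 passed (limma), and Kdr, a receptor of VEGF, had 3.24, -1.46 and -1.81 on the 3 arrays. The list's median of -0.00 and its mean of 0.20 and camera direction (up) were of different sign, and it did not pass (camera adjusted p = 0.323, and adjusted p = 0.830 with an estimated correlation). Without replicate 3 it was called with a median of 0.63 (camera adjusted p = 0.0162), and without replicate 1 its median was -0.72.

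Epithelial, germ cell and trophoblast lists had medians above 0 and passed camera only with the preset correlation. Epithelial genes had a median of 0.63 and 8 of 14 were higher on every array, with 1.21 ± 0.51 (SD, n = 3) for Cdh3 (P-cadherin), the member with the smallest p, 0.83 ± 0.17 for the keratin Krt18 and 0.43 ± 0.63 for Cdh1 (E-cadherin). The list passed camera with adjusted p = 0.00230, and adjusted p = 0.790 with an estimated correlation, with 0 members passing, adjusted over the list alone or over all genes, and the median was 0.42 without replicate 3. Germ cell genes had medians of 0.40, 0.54 and 2.90 on replicates 1, 2 and 3. Hormad1, a protein of meiotic chromosomes with the smallest p, had 2.47 ± 1.86, and 1.40 without replicate 3, Mael 1.71 ± 1.79, Dazl 1.71 ± 1.89 and Ddx4 (Vasa) 1.59 ± 1.5. Over the 3 arrays the germ cell median was 1.10 (camera adjusted p = 0.0185, and adjusted p = 0.821 with an estimated correlation), 7 of 10 members were higher on every array and 0 passed, adjusted over the list alone or over all genes. The germ cell call ended without replicate 2 (adjusted p = 0.0712) and with a dye term (0.0593), and the median was 0.52 without replicate 3 and 1.74 without replicate 1.

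Trophoblast genes, of the embryonic part of the placenta, had a median of 0.73 (camera adjusted p = 0.0220, and adjusted p = 0.790 with an estimated correlation), and the call ended without replicate 2 (median 0.55, adjusted p = 0.242), while the median was 1.13 without replicate 1. Ascl2, a transcription factor of the placenta, rose by 1.53 ± 0.82 (SD, n = 3) adjusted over the list alone, and Prl3d1 (placental lactogen I) had 2.27 ± 1.93. Gcm1, a factor of the placental labyrinth with the smallest p, had 3.07 ± 1.10 and passed adjusted over the list alone, but its probe holds a GAA run of 44 bases and maps to chromosome 7, at 123731567 to 123731626, and a probe of Gcm1 with a run of 10 bases gave 1.25. The other 8 of 10 members did not pass, and over all genes 0 passed (limma). On replicates 1, 2 and 3 the list's medians were 0.06, 1.15 and 1.01, and 4 of 10 members were higher on every array.

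**Figure D3:**
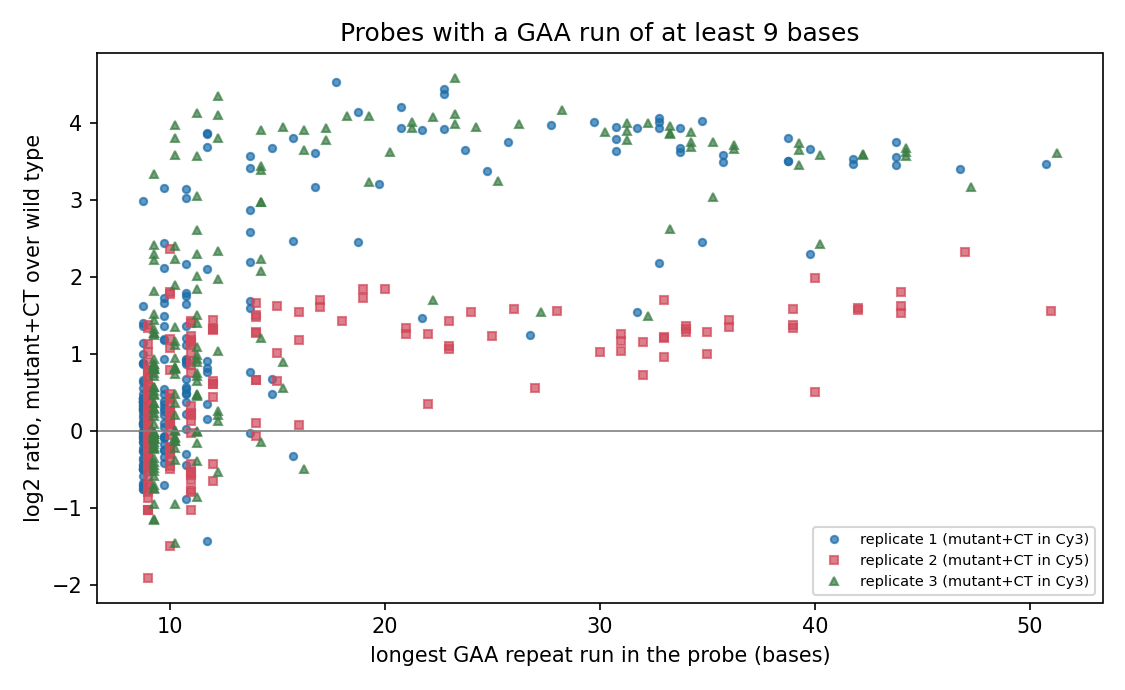
The horizontal axis is the longest GAA run in a probe, from 9 bases on, and the vertical axis the log2 ratio of mutant+CT over wild type on each of the 3 arrays. For the 41 probes with runs of 21 to 60 bases the medians are 3.66, 1.32 and 3.74 on replicates 1, 2 and 3, and for the 26132 probes with runs up to 8 bases 0.01, 0.00 and 0.01.

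The 2-cell-like list, of genes active in the earliest embryo, did not pass, with a median of 0.32 (camera adjusted p = 0.215, and adjusted p = 0.821 with an estimated correlation) and 0 of 6 members passing either way. Tcstv1 had 1.37 ± 0.75. Without replicate 3 the list was called (median 0.48, camera adjusted p = 0.0450), and without replicate 2 its median was 0.05.

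Of the pathway lists, p53 targets had a median of 0.46 and passed camera with adjusted p = 0.00945, and adjusted p = 0.821 with an estimated correlation. Pmaip1 (Noxa), a killer protein with the smallest p, had 1.97 ± 1.45 (SD, n = 3) and 1.17 without replicate 3, Perp 0.91 ± 0.54, Bax 0.61 ± 0.31 and Cdkn1a (p21) 0.11 ± 0.20, and 0 of 15 members passed, adjusted over the list alone or over all genes. The p53 call ended without replicate 3 (median 0.11, adjusted p = 0.148), and the median was 0.79 without replicate 2. Interferon response genes had a median of 0.31 (camera adjusted p = 0.0362, and adjusted p = 0.790 with an estimated correlation). Ifitm3, a membrane protein with antiviral activity and the smallest p, rose by 1.07 ± 0.03 and Oasl2 by 1.48 ± 0.76 adjusted over the list alone, 9 of 11 did not pass, and over all genes 0 passed. The interferon call ended without replicate 1 (median 0.12, adjusted p = 0.422), without replicate 2 (0.48, 0.0712), on Agilent's processed signals (0.34, 0.168), with a dye term (0.34, 0.0593) and with the mean of all probes (0.15, 0.0659), and its median was 0.20 with no filter on dim probes.

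Cholesterol synthesis genes had a median of -0.47 (camera adjusted p = 0.0404, and adjusted p = 0.821 with an estimated correlation), with -1.08 ± 0.38 (SD, n = 3) for Dhcr7 and -1.17 ± 0.85 for Idi1. Stard4, a sterol carrier with the smallest p, rose by 1.64 ± 0.46 adjusted over the list alone, although its other probe gave 0.01 and the mean of both 0.82. The other 15 of 16 members did not pass, and over all genes 0 passed. The call ended without replicate 2 (adjusted p = 0.0712), without replicate 3 (median -0.17, 0.496), on Agilent's processed signals (0.0942) and with a dye term (0.0595), and the median was -0.71 without replicate 1.

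Imprinted genes, expressed from 1 parental copy, moved both ways. Mirg, a non-coding RNA of the Dlk1 to Dio3 region with the smallest p, rose by 3.05 ± 0.65 (SD, n = 3), although its other probe gave 1.449 and Agilent's processed signals 1.45, Meg3 of the same region by 1.39 ± 0.53 and Ascl2 by 1.53 ± 0.82, all adjusted over the list alone, and the other probes of Meg3 gave 4.49 and 1.87. The brightest probe was chosen anew on Agilent's processed signals, so their value for Mirg may come from its other probe. Cdkn1c, a cell cycle inhibitor, fell by 2.62, Nnat (neuronatin) by 2.92, Igf2r by 1.48, Zim1 by 1.25 and Grb10 by 1.23, adjusted over the list alone. The other 12 of 20 members did not pass, over all genes 0 passed (limma), and the list did not pass, with a median of -0.30 (camera adjusted p = 0.593, and adjusted p = 0.908 with an estimated correlation). Without replicate 1 it was called (median -1.06, camera adjusted p = 0.0109), and without replicate 3 its median was 0.39.

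The remaining lists did not pass. Cell cycle genes had a median of -0.04 (camera adjusted p = 0.677, and adjusted p = 0.830 with an estimated correlation), with -1.27 ± 0.34 (SD, n = 3) for Tyms (thymidylate synthase), the member with the smallest p, and -0.14 ± 0.24 for Top2a. Stress and immediate early genes had a median of -0.25 (camera adjusted p = 0.202, and adjusted p = 0.821 with an estimated correlation), with -0.99 ± 0.47 for Atf3 and -0.54 ± 0.12 for the chaperone Hspa5. Hypoxia and glycolysis genes had a median of 0.02, of different sign from their camera direction (down, adjusted p = 0.958, and adjusted p = 0.969 with an estimated correlation), with 1.20 ± 0.63 for Hk2 (hexokinase 2) and 0.02 ± 0.09 for Vegfa. Of the 22, 14 and 20 members of these lists, 0 passed, adjusted over the list alone or over all genes. The stress list was called without replicate 3 (median -0.41, camera adjusted p = 0.0286) and with a dye term (-0.35, 0.0468), and its median was 0.20 without replicate 2, while that of hypoxia and glycolysis was -0.11 without replicate 3.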

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

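Leaving out GAA-repeat probes, scaling the arrays and the separate-channel fit with its correlation estimated without the dye term were chosen after the results were seen; the planned separate-channel fit could not be fitted, because replicate 2 is alone in its dye orientation. Genes changed (0; limma, 3212 at unadjusted p under 0.05) numbered 290 (184 higher, 106 lower) on Agilent's processed signals, 12 (9, 3) with the filter in both channels, 176 (117, 59) with a trended and robust prior, 296 (203, 93) at adjusted p under 0.1, 218 (159, 59) in the separate-channel fit and 0 to 196 (0 to 110, 0 to 86) with 1 array left out, the 196 without replicate 1; the cause was not tested. Every other setting run gave 0. Genes at least 2-fold apart on every array (589; 387 and 202) numbered 1193 (759, 434) on Agilent's processed signals, 774 to 1537 (502 to 965, 272 to 572) with 1 array left out, where fewer arrays must pass, and 529 to 609 under the other settings, while the dye term gives no such count. Quantile normalization of average intensities leaves ratios unmoved by construction. Of the Dido1 probes, 1 passed, 2 on Agilent's processed signals, 0 with the dye term and 0 to 1 with 1 array left out. Of the lists 14 passed, 0 with an estimated correlation, 0 with fry, 10 to 16 with 1 array left out and 10 to 14 under the others. No gene named by rule turned direction under the settings run; other members named in the report were not rerun, and those with both signs across arrays, such as Myl7 and Hand2, depend on the array.

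Medians of some lists turned, for which the cause was not tested. Endothelium (-0.00) had 0.0123 with no background subtraction, 0.0293 with median centring, 0.0375 with no filter, 0.0652 with the filter in both channels, 0.0267 with the dye term, 0.0240 in the deposited table, 0.13 with the mean of all probes, 0.15 with scaled arrays and -0.72 to 0.63 with 1 array left out. Hox genes (0.07) had -0.0304 on Agilent's processed signals, -0.0308 with the dye term and -0.11 to 0.32 with 1 array left out. Smooth muscle (0.15) had -0.00526 with no filter, -0.0749 with the dye term and -0.32 to 0.11 with 1 array left out. Cardiomyocytes (0.19) had -0.20 with the dye term and -0.99 to 0.89 with 1 array left out. With 1 array left out the range was -0.0935 to 0.47 for primitive streak, -0.61 to 1.15 for mesenchyme, -0.97 to 0.0549 for neural crest, -0.41 to 0.20 for stress, -0.11 to 0.0595 for hypoxia and glycolysis and -1.06 to 0.39 for imprinted genes.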

Other observations

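Genes of this part, and its tests of Y-linked dye bias, of turned arrays and of the cardiomyocyte and mesenchyme lists, were chosen only after the results were seen. Some single genes outside the lists, which stand for no group, had low ratios, among them regulators of the early forebrain and neural tube: Fezf1 had a ratio of -4.38 ± 1.62 (SD, n = 3), Fezf2 -3.77 ± 1.42, Dbx1 -3.57 ± 1.07 and Foxb1 -2.83 ± 0.91, and Zic1 had -4.74 ± 2.33. The BMP antagonist Nog had -2.55 ± 0.72. Higher were Tet1, which oxidises methylcytosine (2.08 ± 0.22), the small-RNA effector Ago2 (2.39 ± 0.41) and the RNA-binding protein Igf2bp1 (1.74 ± 0.37). None passed limma with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.0737 for Tet1).

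Genes at least 2-fold apart on every array also lay side by side. A run of 4 on chromosome 3 (88548609 to 88700472, mm9) held probe A_55_P2179448, Syt11, 5830417I10Rik and Gon4l, with ratios of -2.73, -2.82, -4.79 and -1.99, although the other probes of Gon4l gave 0.82 and -0.09, and 2 prolactin runs on chromosome 13 and 2 Xlr runs on X were higher. There were 24 neighbouring pairs in the same direction, against a median of 7 and a highest of 19 in 10000 random placements. The placements treated all genes as independent. Paralogs, such as those of the prolactin and Xlr runs, may share signal between their probes, which was not tested. The count argues against chance placement of independent genes only, and does not decide where paralogs share signal.

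Transcripts without a RefSeq match made up 38.5% of the 387 genes 2-fold higher on every array and 15.3% of the 202 lower ones (odds ratio 3.45), against 25.0% of the other 19800 genes, so the odds ratio joins a higher share among the former with a lower one among the latter. Olfactory receptor probes lay at -0.00959 from equally dim probes. This cannot decide on genomic DNA in the mutant+CT RNA, which could raise the equally dim probes as well. Noise of dim probes is argued against by an odds ratio of 3.56 within 3 ranges of intensity (95% interval 2.29 to 5.54). Probes with GAA runs of 15 to 20 and of 21 to 60 bases had median ratios of 2.88 and 2.96, against 1.52 for 12 to 14 bases. Without these probes the odds ratio was 2.64 (1.67 to 4.28), so they may be part of the pattern but not all of it. Probes with runs of 9 to 11 bases stayed in. Of these, 13 of 113 were 2-fold higher on every array, against 470 of 26132 with runs up to 8 bases. Whether shorter GAA runs account for the rest was not tested. Other repeat units (median 0.222) and purine-rich probes (0.221) were far below the GAA probes, and the opposite strand, CTT (0.773), rests on 2 probes and stays open. A biological difference between the groups was not tested.

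Of the 4 tested genes that RefSeq places on Y, Ddx3y, Rbmy and Uty were lower in mutant+CT on every array and Ube1y1 (0.12) was not; Eif2s3y had -7.245 on replicate 2 and no value on the others, and probes of Zfy1, Zfy2, Usp9y, Kdm5d and Sry were too dim to be tested. A second active X chromosome is argued against by X-linked minus autosomal genes (-0.00299, interval -0.0309 to 0.0269, 838 genes). Dye bias is argued against for Ddx3y, Rbmy and Uty, since it would turn their sign on the dye-swapped replicate 2. There they had -5.356, -3.415 and -1.975. The medians of the 4 genes were -1.584, -2.695 and -1.442 on replicates 1 to 3. The test first used 11 genes with probes on Y, whose medians of -0.17, -0.12 and -0.14 missed its bound of -1. The set was changed after this was seen. Loss of Y in part or all of the cells, or another line of origin, is a candidate explanation that was not tested. Rbmy and Uty were not well above background in mutant+CT on any array, so loss in part of the cells cannot be told from loss in all. Another line of origin would bear on the other genes and lists as well.

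Cardiomyocyte and mesenchyme lists were high on replicate 1 alone. Dye bias is argued against, as replicates 1 and 3 share a dye orientation and differ by at least 1.93 in both medians. Loess sets the median over all genes near 0 on every array (0.0138 on replicate 1), and the list medians were taken after it. A shift of all genes alike on replicate 1 is thus removed and does not account for these lists. On that array visceral endoderm (1.37), primitive streak (1.24) and endothelium (1.23) also had medians over 1, while neural progenitors (-2.30) and primitive and parietal endoderm (-1.72) lay below -1. A hypothesis is that the replicates may differ in how many cells became mesoderm, which was not tested.

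The 589 genes at least 2-fold apart compare with a highest of 179 when 1 array is turned, which is the dye split, and this was 1 of 4 sign patterns, while for genes past the adjusted threshold all 4 gave 0 (highest other 0; limma, 3212 at unadjusted p under 0.05); 4 patterns are too few for a share under 0.05. Dye bias as the source of the 589 is argued against by the correlation of 0.333 between replicate 2 and the mean of the others.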
